A study of Homo sapiens with 8 samples.

How the data were processed

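RNA of 22Rv1 cells was sequenced after preparation with an mRNA library kit, per the labels' protocols, 4 libraries with the miR-194 mimic and 4 with the negative control, and the groups and replicate numbers were taken from the sample titles. The deposited table holds raw read counts per gene symbol for the 8 libraries, 23346 symbols of which 3370 had no count in any library, as the values and the sheet name show. The submitters' processing notes name cutadapt 1.8.1, FastQC, STAR, R 3.2.3 and edgeR 3.3 and the build hg19, without saying what each did. The counting program, the gene annotation, the strand setting and the treatment of reads shared by similar or overlapping genes are not given in the sources used here. Library totals ran from 32485036 to 47248241 counts, a ratio of 1.45, so a floor of 3 counts corresponds to 0.0635 to 0.0924 CPM, and such floors cover counting error only. Mature miR-194 itself was not analysed here.

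Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM normalisation, robust quasi-likelihood fit, Benjamini-Hochberg adjustment, threshold 0.05), with the group as the only term. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM, counts scaled to a common library total, use TMM library sizes, and log2 values of single libraries have a prior count of 2. Gene lists fixed before the data were examined were tested with limma 3.58.1 (camera, two-sided, preset correlation 0.01, lists with at least 5 tested genes, 17 of 20), again with an estimated correlation, and with fry. With an estimated correlation camera called 0 lists, and 2 had an unadjusted p below 0.05. Sites and 7mers were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. Mitochondrially encoded transcripts had no row in the table under the symbols searched. DESeq2 1.42.0 and limma-voom served as alternatives.

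Sites were searched in the longest 3' UTR of at least 50 bases of each gene in GENCODE 29 (GRCh38), which is not the build of the deposited counts, so genes were joined by symbol alone. Of the symbols, 20194 were the same in GENCODE 29, 1465 were matched by a RefSeq synonym and 1687 were not matched, and 89.6% of the tested genes had a 3' UTR. Site positions are from this match and count from 1. Matched comparisons used 10 bins of length and 5 of GC content. The 7mer scan removed trends of the fold change with log length and GC content (each with its square), limited residuals to 1 on the log2 scale and used 7mers in at least 50 genes. The motifs GACGTA and GACAGTA were picked from that scan, after the data were seen.

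Genes named in the text followed a rule fixed before the data were examined: the 10 largest changes in each direction among genes past the threshold with a mean log2 CPM of at least 3 and no overlap between the groups, then FOXA1 and SOCS2, then up to 4 members of each list with the smallest p, and the 5 smallest p in each direction. Of the genes picked, 5 are not reported here, and none took their places.

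The steps were tested on simulated data. With counts drawn for the 14977 tested genes of this comparison, edgeR recovered 44% of 50 genes changed 1.25-fold, 82% of those changed 1.5-fold, 94% at 2-fold and 100% at 3-fold. Of its calls 6.43% were false. Among all the changed genes, called or not, 2 had a fold change in the wrong direction. The simulation changed a far smaller share of the genes than the 38.1% called in the data. The adjustment depends on that share, so the recovery in the data may differ. A list shifted 1.25-fold was called and 0 of the other lists were. Each gene was drawn independently of the others, so this check says nothing on lists whose genes vary together. In the scan of 13423 genes, 5 of 5 7mers planted with a log2 shift of 0.15 on shuffled fold changes ranked first. They were drawn from 7mers held by more genes than TGACGTA (219 genes) and GACGTAA (159), which are reported below. The check therefore says nothing on 7mers that rare. Replicates of a group differed by more than counting noise (chi-square per degree of freedom from 3.98 to 18.9), so each was kept as a sample.

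The replicate numbers are shared between the groups. Same-numbered libraries deviated together from their group means, with correlations of 0.27, 0.34, 0.18 and 0.43, so each met the rule set for pairing, a correlation above 0.1. Mimic replicate 1 correlated with control replicate 2 at 0.26 and mimic replicate 2 with control replicate 1 at 0.28. Mimic replicate 3 correlated with control replicate 4 at 0.20 and mimic replicate 4 with control replicate 3 at 0.32. These exchanged pairs met the same rule, so the correlations show replicates 1 and 2 against 3 and 4. They do not single out the same-numbered pairs. The pairing by number therefore rests on the shared numbers, and the labels name no shared day or batch. Alternatives covered normalisation, filters, tests, the replicate block, the removal of each library and, for the sites, site class, 3' UTR choice and matching.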

Results

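RNA was sequenced from 22Rv1 cells, an established human prostate cancer line that grows without added androgen. The cells had received either a double-stranded RNA that mimics the microRNA miR-194 or a negative control RNA, each at 20 nM, and were collected 36 h later. There were 4 libraries per group. The total count per library ran from 32485036 to 47248241 over 23346 gene symbols, and EEF1A1, the most abundant gene in each library, took at most 0.645% of the counts. The series title places the comparison in the question of how miR-194 acts after transcription during a shift of prostate cancer cells towards a neuroendocrine state. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples. No untransfected library was analysed here, so a gene that is higher in the mimic libraries is equally one that is lower in the control libraries.

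The genes with the largest falls in the mimic libraries had varied known roles. PPP1R14B, an inhibitor of protein phosphatase 1, fell from 204 ± 7.58 to 45.8 ± 1.81 CPM (counts scaled to a common library total, mean ± SD, n = 4 in each group), a log2 fold change of -2.16 ± 0.04 (SE). BCKDHA, a subunit of the branched-chain keto acid dehydrogenase, fell by 1.86. FZD6, a Wnt receptor, had a log2 fold change of -1.85 ± 0.04 (SE), and IL6ST, the gp130 subunit shared by receptors of the interleukin 6 family, of -1.74 ± 0.05. Other genes with large falls were TMEM194A at -2.05, FAM63B at -1.82, MRS2, a mitochondrial magnesium channel, at -1.80, TMED5 at -1.73 and ARL6IP5 at -1.72. BTF3L4, named for its small p, fell by 1.64.

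The 10 genes with the largest rises also had varied known roles. PDK4, a kinase that shuts down pyruvate dehydrogenase, rose to 47.8 ± 4.98 CPM (SD, n = 4), a log2 fold change of 1.87 ± 0.08 (SE). PTPMT1, a mitochondrial phosphatase of cardiolipin synthesis, rose by 1.79, DDX3Y, an RNA helicase encoded on the Y chromosome, by 1.61 and PPP2R1B, a scaffold subunit of protein phosphatase 2A, by 1.42. RHOB at 1.37, BANF1, a chromatin-binding protein of the nuclear envelope, at 1.33, PDCD6 at 1.31, MAPK4 at 1.26, SLC36A1 at 1.22 and NRBF2 at 1.21 completed the 10, and CCNC at 1.10 and DUSP16 at 0.88 were named for their small p. DDX3Y has a close copy on the X chromosome, and how reads shared by such copies were counted is not given in the sources used here. Of these 10 genes, 7 carried GACGTA or GACAGTA in the 3' UTR, against 12.5% of the tested genes with a 3' UTR, and 1 carried an 8mer or 7mer miR-194 site. Both motifs were picked from a scan of these data.

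Of 14977 genes tested, 5712 changed at an adjusted p below 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2737 of them higher and 2975 lower with the mimic. Most of the changes were small. The median absolute log2 fold change of the called genes was 0.30, and 188 genes changed at least 2-fold, 128 lower and 60 higher. Among the called genes, 5036 had no overlap between the 4 mimic and the 4 control values, and 36.9% of all tested genes had none, where chance gives 2.86%. The libraries also parted by replicate number, with replicates 1 and 2 on one side of the second principal component and replicates 3 and 4 on the other (20.6% of the variance, against 51.1% for the first component, which separated the groups). Within replicates 1 and 2 alone 5107 genes changed, and within replicates 3 and 4 alone 4995. The count of genes changed at least 2-fold was 99 with a mean log2 CPM of at least 3.

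**Figure D1:**
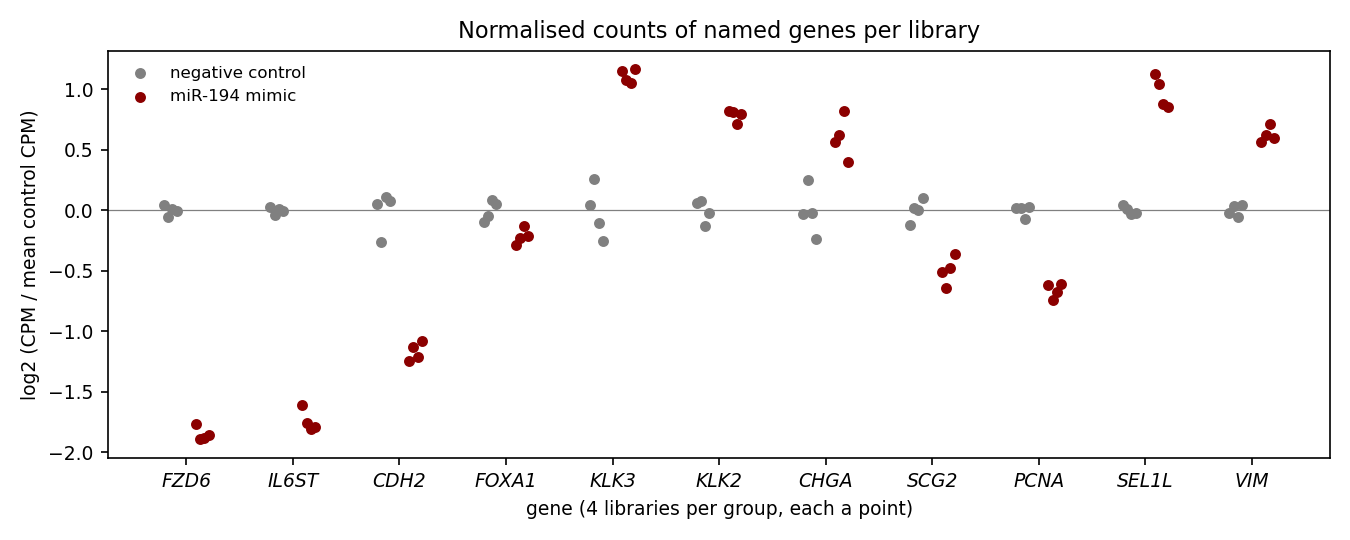
CPM of 11 named genes in the 8 libraries, each point 1 library, as log2 of the ratio to the mean of the 4 control libraries. The mimic points of FZD6, IL6ST and CDH2 lie below those of the control, and those of KLK3, KLK2 and SEL1L above.

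Genes with a site for miR-194 were lower in the mimic libraries. A site is a match to the 5' end of the guide strand, miR-194-5p, in the longest annotated 3' UTR (GENCODE 29, GRCh38), and 2746 of the 13423 tested genes with a 3' UTR held an 8mer or 7mer site. The median log2 fold change was -0.19 for 566 genes with an 8mer site (CTGTTACA), -0.10 for 1010 with a 7mer-m8 site, -0.11 for 1170 with a 7mer-A1 site, -0.01 for 1663 with a 6mer site, and 0.04 for 9014 genes with none. In each library the median centred log2 CPM of the site genes was set against that of genes without a site. This difference was -0.09 ± 0.03 in the mimic libraries and 0.08 ± 0.02 in the control libraries (SD, n = 4 each, two-sided exact permutation p = 0.0286, the smallest that 4 against 4 libraries allow). With the replicate block, the sign-flip permutation p was 0.125, the smallest that 4 pairs allow, so the paired test cannot pass. The mimic-minus-control difference was -0.13 within replicates 1 and 2 and -0.19 within replicates 3 and 4. Of the genes that fell, 41.0% had an 8mer or 7mer site, of those that fell at least 2-fold 76.1%, of those that rose 11.9%, and of those not called 16.3%.

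**Figure D2:**
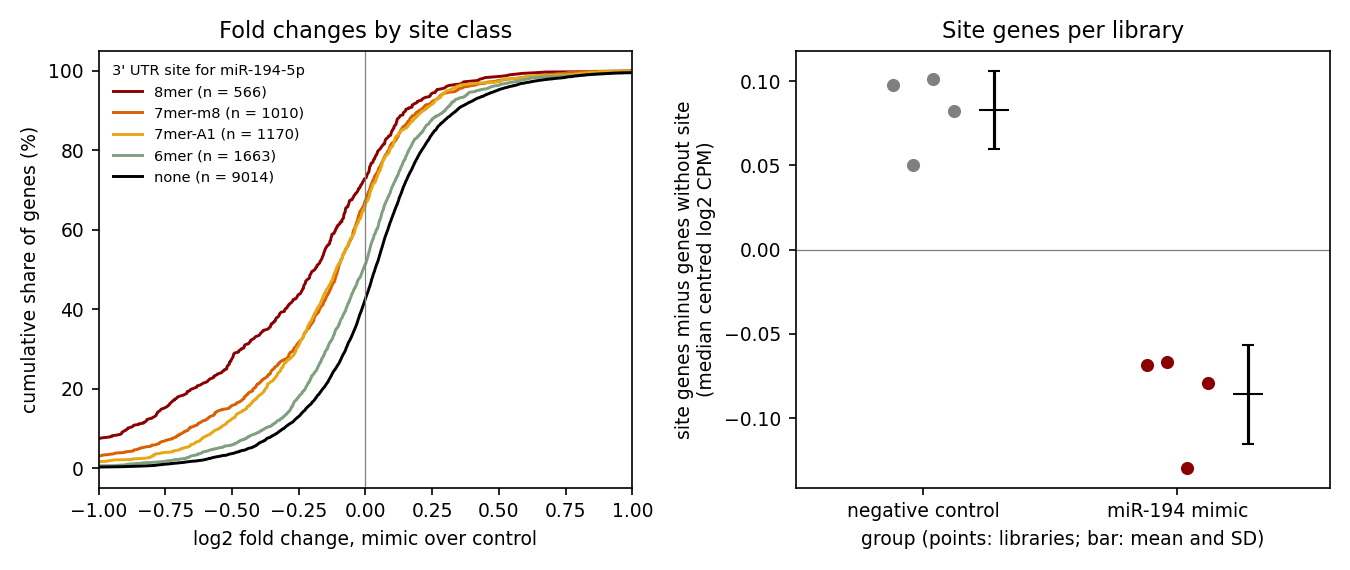
Left, cumulative share of genes (percent) against log2 fold change for genes with an 8mer, 7mer-m8, 7mer-A1, 6mer or no site for miR-194-5p in the 3' UTR, with the axis limited to changes of up to 2-fold. Right, the difference between site genes and genes without a site in each library, with mean and SD, where the 4 mimic libraries lie below 0 and the 4 control libraries above.

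Of the 9 genes named for the size of their fall, 8 had an 8mer or 7mer site. The FZD6 3' UTR held an 8mer site at chromosome 8, 103331587 to 103331594, and a 7mer-A1 site at 103331545 to 103331551 (GRCh38, plus strand). The IL6ST 3' UTR held an 8mer site at chromosome 5, 55937076 to 55937083 (minus strand), beside 3 7mer-A1 sites, and also a GACAGTA at 55956125 to 55956131. In this longest annotated 3' UTR the GACAGTA lay at position 88 and the nearest 7mer-A1 site at 4289. They lie further apart on the genome, so an intron separates them, and whether the transcripts present here hold both was not tested. PPP1R14B had no site in its 3' UTR and an 8mer match in its coding sequence. A scan of 16260 7mers placed TGTTACA and CTGTTAC, both parts of the 8mer site, at the lowest ranks, with z of -22.2 and -21.8 across genes, which are not independent replicates. At the other end stood GACAGTA with z of 10.2, TGACGTA with 9.85 and GACGTAA with 8.92. None of these is a part of the miR-194-5p site. Genes with GACGTA or GACAGTA and no 8mer or 7mer site for miR-194-5p numbered 1072, of which 430 rose and 114 fell. Their difference from genes without the motifs was 0.11 higher in the mimic than in the control libraries (SD 0.02 in each group, n = 4 each). No p is given for this difference, since the motifs were picked for it in the same libraries.

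**Figure D3:**
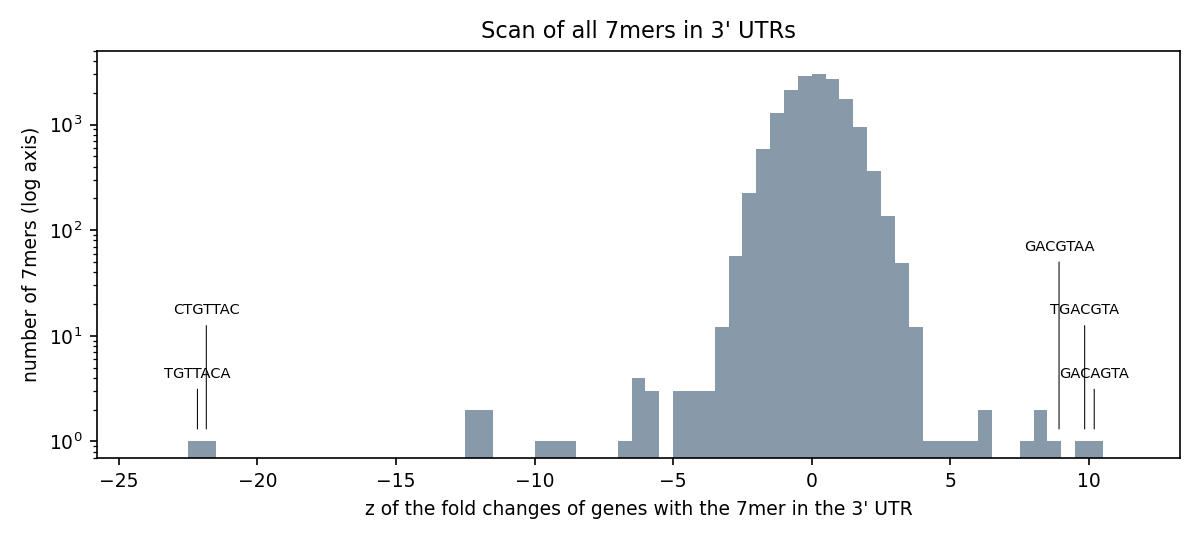
Distribution of the z of 16260 7mers on a log axis of counts, each z comparing the fold changes of genes with and without the 7mer in the 3' UTR after removal of trends with its length and GC content. TGTTACA and CTGTTAC stand alone at the low end, and GACAGTA, TGACGTA and GACGTAA lie at the high end.

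Most genes given as direct miR-194 targets in earlier reporter assays fell. Of 22 tested, 17 fell, 1 rose and 4 did not pass, and the same numbers, 17 and 1, passed when adjusted over the list alone. The median log2 fold change was -0.44, and limma's camera test gave adjusted p = 1.6e-08, against adjusted p = 0.0649 with an estimated correlation. FOXA1 and SOCS2 are on the list and were named here in advance as genes of interest, and whether any member was first picked from these libraries is not given in the sources used here. Each of the 22 has an 8mer or 7mer site in its 3' UTR. The median was -0.42 within replicates 1 and 2 and -0.49 within replicates 3 and 4. Beside FZD6, the members with the smallest p were CUL4B, a ubiquitin ligase scaffold, at -0.91, AKT2 at -0.45 and HBEGF, a ligand of the EGF receptor, at -1.34. FOXA1, a pioneer factor of luminal prostate cells with a 7mer-m8 site at chromosome 14, 37591193 to 37591199 (GRCh38, minus strand), fell from 407 ± 23.1 to 350 ± 15.5 CPM (SD, n = 4 each), a log2 fold change of -0.22 ± 0.05 (SE). SOCS2, a suppressor of cytokine signalling, averaged 0.815 CPM in the mimic and 0.869 in the control libraries. Its log2 fold change of -0.11 ± 0.24 (SE) did not pass.

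The androgen response genes did not pass the test as a group. Of 33 androgen response genes, 8 rose and 8 fell, and 10 and 9 did so adjusted over the list alone, with camera adjusted p = 0.704. The list's median was -0.02, while its mean was 0.06 and the camera direction was up. Of 32 members with a 3' UTR, 12 (37.5%) had an 8mer or 7mer site, against 20.5% of the tested genes with a 3' UTR. These 12 had a median of -0.22. The 20 members without such a site had a median of 0.13, and 6 of them rose and 2 fell. This difference within the list was not tested. KLK3, which encodes prostate-specific antigen, rose by 1.11 from 5.40 ± 0.833 CPM (SD, n = 4), and KLK2, a kallikrein of close sequence, rose by 0.79 although it had a 7mer-A1 site. How reads shared by this pair were counted is likewise not given. HPGD, a prostaglandin dehydrogenase, fell by 0.55 and ZBTB10 fell by 0.70, and both had a miR-194 site. Of 24 luminal epithelial genes, 12 rose and 1, FOXA1, fell, and 15 and 2 did so adjusted over the list alone, with a median log2 fold change of 0.14. The camera test gave adjusted p = 0.00423, against adjusted p = 0.334 with an estimated correlation, and the median was 0.11 within replicates 1 and 2 and 0.19 within replicates 3 and 4. KRT18 rose by 0.42 although its 3' UTR held an 8mer site, ELF3 rose by 0.34, EPCAM by 0.27 and GATA2 by 0.19.

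Neuroendocrine genes moved in both directions. Of 22 markers tested, 2 rose, 2 fell and 18 did not pass, over all genes and adjusted over the list alone, with camera adjusted p = 0.834. The median was slightly below 0, the mean was 0.01 and the camera direction was up. CHGA and CHGB, proteins of secretory granules, rose by 0.61 and 0.41, while SCG2, another granule protein, fell by 0.49. ELAVL3, a neuronal RNA-binding protein with a 7mer-m8 site, fell by 0.68. Within replicates 3 and 4 alone ELAVL3 kept a log2 fold change of -0.65 and did not pass. Of 30 regulators tied to neuroendocrine prostate cancer, 23 were tested. Of these, 2 rose and 7 fell, over all genes and adjusted over the list alone, with camera adjusted p = 0.293. The fry test, which does not compare a list with other genes, gave adjusted p = 0.0191 with direction down. The median was -0.05, with -0.13 within replicates 1 and 2 and 0.02 within replicates 3 and 4. With 1 library left out the median ran from -0.13 to 0.04. CBX5, a heterochromatin protein, PEG10, a retrotransposon-derived gene, and ONECUT2, a homeodomain factor, fell by 0.62, 0.62 and 0.49, and each had an 8mer or 7mer site. AURKA, a mitotic kinase with no site, fell by 0.41.

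Most genes of the cell cycle lists fell in the mimic libraries. Of 28 G1/S genes, 24 fell and 2 rose, and 26 and 2 did so adjusted over the list alone, with a median log2 fold change of -0.30 and camera adjusted p = 3.47e-10, against adjusted p = 0.334 with an estimated correlation. SLBP, which binds histone mRNA, fell by 0.85, GINS1, of the replicative helicase, by 0.71, PCNA, the sliding clamp of DNA polymerase, by 0.66 and FEN1, a flap endonuclease, by 0.46. Of 28 G2/M genes, 25 fell and none rose, over all genes and adjusted over the list alone, with a median of -0.30 and camera adjusted p = 3.47e-10, against adjusted p = 0.446 with an estimated correlation. HMMR fell by 0.72, KIF2C by 0.50, CCNB2, a mitotic cyclin, by 0.44 and BUB1B, a spindle checkpoint kinase, by 0.41. Over both lists the median was -0.31 within replicates 1 and 2 and -0.31 within replicates 3 and 4. Of 56 members, 6 (10.7%) had an 8mer or 7mer site in the 3' UTR, SLBP, GINS1 and FEN1 among them, and the median of the other 50 was -0.28. Of the others named here, PCNA, HMMR and BUB1B had a 7mer-m8 match in the coding sequence, CCNB2 a 6mer site and KIF2C neither. Both lists were also lower in replicates 3 and 4 than in replicates 1 and 2, with the group as a term, by a median log2 of -0.08 for G1/S and -0.12 for G2/M, with camera adjusted p of 7.47e-05 and 1.38e-08, against adjusted p of 0.377 and 0.344 with an estimated correlation.

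Among endoplasmic reticulum stress genes, more rose than fell. Of 25 genes of the unfolded protein and integrated stress responses, 13 rose, 1 fell and 11 did not pass, over all genes and adjusted over the list alone, with a median log2 fold change of 0.22 and camera adjusted p = 0.000432, against adjusted p = 0.499 with an estimated correlation. SEL1L, of the machinery that degrades misfolded proteins, rose by 0.98 and PDIA4, a disulfide isomerase, by 0.93, and both carried GACAGTA in the 3' UTR. PDIA6 rose by 0.20 and TRIB3 by 0.30, and neither carried the motifs. Of the 25 genes, 3 carried GACGTA or GACAGTA. The other 22 had a median of 0.20, and 10 of them rose. The median of all 25 was 0.29 within replicates 1 and 2 and 0.13 within replicates 3 and 4. With the group as a term, the list was also lower in replicates 3 and 4 than in replicates 1 and 2, by a median log2 of -0.14 (camera adjusted p = 0.00987, against adjusted p = 0.490 with an estimated correlation). Of 23 hypoxia genes, 8 rose and 2 fell, over all genes and adjusted over the list alone, with a median of 0.12 and camera adjusted p = 0.0373, against adjusted p = 0.287 with an estimated correlation. The estimate for this list was -0.0023, below the preset 0.01. The unadjusted camera p was 0.0338 with the estimate, against 0.0132 with the preset. EGLN3, a HIF prolyl hydroxylase, rose by 0.98, HK2, a hexokinase, by 0.49, KDM3A by 0.43 and ENO1 by 0.27. The camera call was lost without mimic replicate 4 (adjusted p = 0.0554), without control replicate 2 (adjusted p = 0.0577) and within replicates 1 and 2 (adjusted p = 0.0707). With 1 library left out the adjusted p ran from 0.0176 to 0.0577. The median was 0.08 within replicates 1 and 2 and 0.13 within replicates 3 and 4.

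Other pathways had members that rose and members that fell, with camera adjusted p from 0.293 to 0.880 for the lists of this paragraph. Of 18 mesenchymal genes, 7 rose and 1 fell. VIM, an intermediate filament, rose by 0.63, FN1, fibronectin, by 0.64 and ITGA5 by 0.31, while CDH2, N-cadherin, fell by 1.16 from 5.03 ± 0.564 CPM (SD, n = 4). CDH2 had a 7mer-A1 site in its 3' UTR. Of the 16 mesenchymal members without an 8mer or 7mer site in the 3' UTR, 7 rose and 0 fell, with a median of 0.03. Of 23 JAK-STAT genes, 5 rose and 4 fell. IL6ST fell, and STAT3, SOCS7 and PTPN6 rose by 0.35, 0.42 and 0.21. This list had a median of 0.02 and a mean of -0.05, and the camera direction was up. Of 23 p53 targets, 6 rose and 10 fell, among them BTG2 at -0.70, PMAIP1 at -0.70, DDB2 at -0.46 and CCNG1 at -0.24. Of 29 interferon response genes, 4 rose and 6 fell, with RSAD2 at -0.86, PSMB9 at -0.68, OAS3 at -0.47 and TAP1 at -0.45. Of 24 cholesterol synthesis genes, 7 rose and 4 fell, with HMGCS1 at 0.39 and MSMO1 at 0.29 against FDPS at -0.33. Of 16 small RNA machinery genes, 4 rose and 4 fell, with TNRC6C at 0.51, XPO5 at 0.15, EIF2C4 at -0.24 and RAN at -0.20. For each of these lists the counts were the same adjusted over the list alone. The fry test, which does not compare a list with other genes, gave adjusted p = 0.000583 for the mesenchymal list, with direction up. It gave adjusted p of 0.0176 for JAK-STAT, 0.0188 for interferon response and 0.0259 for p53 targets, with direction down. Cholesterol synthesis and small RNA machinery did not pass fry, with adjusted p of 0.390 and 0.360.

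Markers of other cell types varied in level. Of 16 basal epithelial and 15 fibroblast and smooth muscle genes, 8 of each had enough counts to be tested. Among the markers named here, control means ran from 0.401 CPM for PDGFRB to 70.1 for DST, with LUM at 32.1. Of 8 basal epithelial genes tested, ITGA6 fell by 0.38, and LAMB3 and DST had log2 fold changes of 0.25 and 0.09 that did not pass. With replicates 1 and 2 against 3 and 4 as a term, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called LAMB3 (adjusted p = 0.0450, range 0.0450 to 0.508 over the alternatives). Of 8 fibroblast and smooth muscle genes, COL1A1 rose by 0.26 and ACTA2 fell by 0.85, and LUM and PDGFRB did not pass. Within replicates 1 and 2 alone COL1A1 kept a log2 fold change of 0.21 and did not pass. Counts over these lists were the same adjusted over the list alone, and camera gave adjusted p of 0.834 and 0.868. Too few genes were tested for a list test of leukocyte markers (3 of 15) and endothelial markers (1 of 12). CD68, a lysosomal protein also made outside leukocytes, rose by 0.78, and CD14 and ESAM did not pass.

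**Figure D4:**
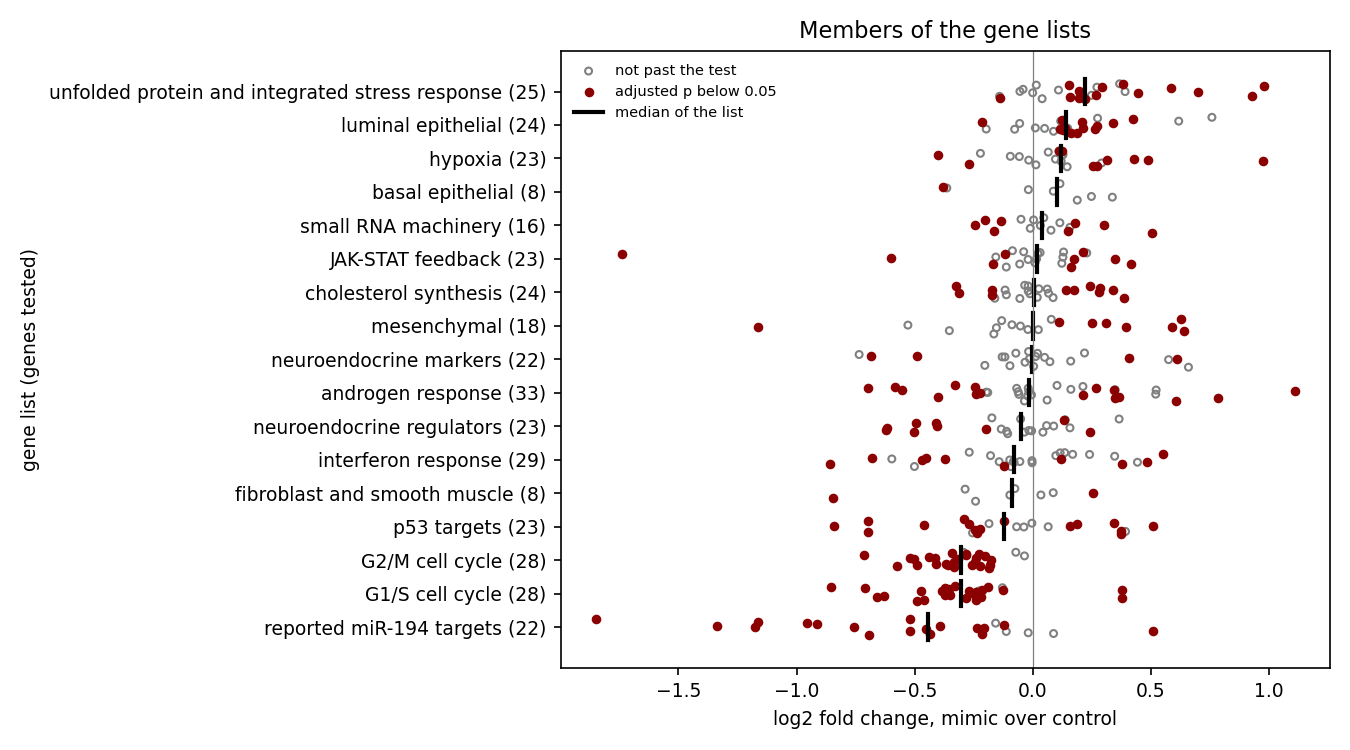
Log2 fold change of the members of the 17 gene lists with at least 5 tested genes, each point 1 gene, filled where it passed the test, with the median of each list as a bar. The reported miR-194 targets have the lowest median and the unfolded protein and integrated stress response the highest.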

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

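In 12 of 186 groups of 4 libraries, 1 library stood apart from the other 3 by a gap to the nearest value, divided by the whole range, above Dixon's critical value. Chance gives about 9.3 such groups, or 1 in 20. In the mimic group these were AKT2 in replicate 2 (0.866), ONECUT2 in replicate 3 (0.962), TAP1 in replicate 4 (0.929), HK2 in replicate 2 (0.913) and DUSP16 in replicate 2 (0.917). In the control group they were PPP2R1B in replicate 2 (0.83), FAM63B in replicate 4 (0.866), HBEGF in replicate 3 (0.891), KRT18 in replicate 1 (0.862), CDH2 in replicate 2 (0.841), SLBP in replicate 3 (0.933) and PCNA in replicate 3 (0.929). Several ranges were narrow, as for SLBP, where control replicate 3 had a log2 CPM of 7.13 and the others 7.24 to 7.25.

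The weighing of 3 patterns follows. The test of reverse complements, and the reduced versions of the 7mer comparison, were chosen after the result was seen.

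Genes with a miR-194-5p site were lower in the mimic libraries. Matching on 3' UTR length and GC content left a shift of -0.1759, against -0.17 unmatched, which argues against those properties as the cause. Genes with a site for the passenger strand and none for the guide shifted by 0.01176 (two-sided exact permutation p = 0.4), and by -0.01 when matched, so a small effect of the passenger strand stays open. Genes with a coding site and no 3' UTR site shifted by -0.0697 (two-sided exact permutation p = 0.0571), which missed the threshold and also stays open, although 23.3% of them fell against 11.9% of genes with neither. Of the 35 splits of the 8 libraries, 1, the real one, gave as many as 5712 changed genes. The highest other gave 147, with mimic replicate 4 and control replicate 2 exchanged. The split of replicates 1 and 2 against 3 and 4 gave 119. Where the pairing by replicate number is set aside, this argues against chance assignment of libraries for the count of genes. With the pairing kept, the real split can be compared only with the 7 others that part all 4 same-numbered pairs. Those 7 gave 0, but so few splits cannot pass a test, so chance assignment within the pairs stays open.

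Genes with GACGTA or GACAGTA in the 3' UTR were higher in the mimic libraries. The reverse complements shifted by 0.002879 against 0.11 for the motifs as written, which were picked for their rise, and this argues against a DNA element that works in both orientations. Competition with endogenous microRNAs stays open. The 10 examined were taken as abundant in epithelial cells, and their levels in these cells were not measured here. Of these, 0 had site genes that rose past the threshold in the exact library permutation (0 also at an unadjusted p below 0.05), but 8 shifts lay above 0 (largest 0.02). With matching, 4 reached the smallest p the design allows (Benjamini-Hochberg adjusted p = 0.0714), and passing needed at least 6 at that p, since 5 give 0.0571. A candidate explanation is that the negative control RNA lowers genes that match its own seed, but the highest z of the real split, 10.33 (from differences of mean log2 CPM, as in the other splits, not from the edgeR fold changes of the report), did not pass the bound set beforehand over all 7mers in either direction, 21.0, a bound that was poorly chosen because the miR-194 sites themselves set it in splits with 3 control libraries on one side. With those 7mers left out, a reading chosen after the scan was seen, the highest of the splits with 2 mimic libraries on each side was 6.667, and that of the splits with 3 was 9.391, where the top 7mers were the motifs themselves and the value is no measure of chance, while the labels give neither the control's sequence nor an untransfected sample, so effects of the control and of the mimic on these genes cannot be told apart.

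Cell cycle genes were lower in the mimic libraries. Members with no 8mer or 7mer site in the 3' UTR had a median of -0.2808 against -0.30 for all 56. This argues against direct 8mer or 7mer sites in the members' 3' UTRs as the main cause. Some of these members had other matches, as PCNA, HMMR and BUB1B in the coding sequence and CCNB2 a 6mer site. Coding matches were not weighed for this pattern and stay open. The median nearer 0 of those within replicates 1 and 2 and within replicates 3 and 4 was -0.3087, so the fall was present in each part. Each part holds as many mimic as control libraries, so a difference between the parts alone could not make the groups differ. The value therefore does not weigh the split of the replicates as a cause. An indirect effect of the mimic on proliferation, or of the control in the other direction, was not tested.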

How the results depend on the processing

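Alternatives on replicates 1 and 2 against 3 and 4, and the comparison without genes carrying GACGTA or GACAGTA, were chosen after seeing the data, and the others before the data were examined. Under each setting run, no called gene changed sign and the counts of changed, higher and lower genes stayed within 1.5 times. Leaving out 1 library gave 4845 to 5448 changed genes, 2305 to 2722 higher, 2540 to 2796 lower and 181 to 222 changed at least 2-fold. The last count was 99 with a mean log2 CPM of at least 3, where fewer genes were tested. With the replicate block, 7616 genes changed (3778 higher and 3838 lower, 193 at least 2-fold), 6 calls were lost, the number of called lists stayed at 6, and the site shift kept its value with a sign-flip p of 0.125, the smallest that 4 pairs allow. The block changed no call of a gene named in the text or of a list.

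The camera test called 6 lists. It called 0 with an estimated correlation (2 at an unadjusted p below 0.05), and fry, which does not compare a list with other genes, called 11. Leaving out 1 library gave 5 to 6. Site genes differed by -0.178 to -0.156 when 1 library was left out, and by -0.131 in replicates 1 and 2 alone, where 2 against 2 libraries cannot pass a test. The cause of these differences was not tested.

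Directions turned only for results that were not called with all 8 libraries. By list, with adjusted p under the alternative, these were neuroendocrine markers (0.944, replicates 1 and 2), basal epithelial (0.969 without control replicate 2, range 0.706 to 0.969 with 1 library left out), fibroblast and smooth muscle (0.855, replicates 3 and 4) and JAK-STAT (0.0176 with fry, 0.997 and 0.982 without control replicate 3 or 4, range 0.783 to 0.997). By gene, the log2 fold change of SOCS2 became 0.0144 without mimic replicate 4, 0.00857 without control replicate 1 and 0.0116 in replicates 3 and 4 (range -0.301 to 0.0144 with 1 library left out), that of PDGFRB 0.00643, of CD14 0.201 and of ESAM 0.0183 in replicates 3 and 4, and of CD14 0.0516 without control replicate 2 (range -0.189 to 0.0516). These 4 genes averaged at most 1.70 CPM in either group, and whether depth is the cause was not tested.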

Other observations

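This contrast was chosen after the split of the replicates was seen. Replicates 3 and 4 differed from replicates 1 and 2 in 3282 genes, 1522 higher and 1760 lower, in edgeR's quasi-likelihood test with the group as a term. Beside the cell cycle lists, camera called 4 lists in this contrast. The unfolded protein and integrated stress response had a median of -0.14 (camera adjusted p = 0.00987), neuroendocrine regulators -0.11 (camera adjusted p = 0.00772), cholesterol synthesis -0.11 (camera adjusted p = 3.88e-06) and p53 targets 0.07 (camera adjusted p = 0.0199). With an estimated correlation camera called 0 lists in this contrast (2 at an unadjusted p below 0.05). The labels give passages without saying which library had which.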
